A study of Homo sapiens with 12 samples.

How the data were processed

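Small RNA from K562 cells was sequenced in 12 libraries, 3 each of sgNT, sgCYRANO, WT and ZSWIM8 KO. Total RNA was isolated with a miRNeasy kit and libraries were made with a NEBNext small-RNA kit, per the labels' protocols. The submitters' processing notes name bcl2fastq, FastQC 0.11.2, STAR, featureCounts, edgeR and the genome build hg19, without giving their roles or order. How reads shared between microRNA copies or near-identical family members were counted is not given in the sources used here, so members of such families are uncertain.

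The data used were the authors' deposited tables of their own edgeR comparisons, 1 per comparison. Per the file headers, each microRNA has a log2 fold change and a mean log2 CPM, both on the log2 scale, an F statistic, used here as a score, an unadjusted p-value and an adjusted p-value deposited by the authors. The design had assumed another unit, counts per library, and for counts had set TMM scaling in edgeR, alternatives in DESeq2 and limma-voom, replicate blocks and left-out libraries, which were not run. The files held the authors' comparisons, for which the design set the deposited tests as the main result. The headers do not say which group is the numerator, and the second-named group was taken as the numerator.

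What the tables rest on was tested on their values. Benjamini-Hochberg adjustment over all rows gave the deposited adjusted p-values to within 5.5e-08 and 1.09e-06, so the rows are all the microRNAs that were tested. Inverting the mean log2 CPM (prior count of 2) and the log2 fold change (prior count of 0.125) gave mean CPM values for each group that sum to 1000000 in all 4 groups. The test was therefore fed values that had already been scaled to library totals, with no sign of a further composition factor. A consequence is that the counting part of the variance was set as if every library held 1000000 reads. The degrees of freedom implied by F and p were most often 3348 in the first table, which is 4 residual degrees times 837 microRNAs and the value for a fit of 6 libraries in 2 groups with no block, and most often 164.1 in the second.

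Depth was read from the smallest values. A group mean at low CPM is a sum of whole reads, each worth a fixed CPM step per library, and 3 steps per group accounted for 196 of 196 low values in sgNT, 177 of 179 in sgCYRANO, 208 of 208 in WT and 180 of 183 in ZSWIM8 KO within 0.0015 CPM. Steps moved at random by up to 10% accounted for 5.96%, 10.00%, 2.80% and 10.6% on average over 1000 draws. The totals cannot be tied to replicate numbers. The group totals were 5490000, 5290000, 3810000 and 7060000, in that order. With the fold changes turned, the totals of sgNT and sgCYRANO, and those of WT and ZSWIM8 KO, would change places. The median standard error of a log2 fold change at 10 to 30 CPM was 0.26 in the first table and 0.37 in the second, and at 1000 CPM or more 0.09 and 0.10.

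Standard errors were taken as the log2 fold change over the normal deviate of the deposited p, and 95% intervals from them. Ratios of errors to those of microRNAs of like abundance used instead the log2 fold change over the root of the deposited F, with a running median over microRNAs of neighbouring abundance. The difference between both comparisons, and between the arms of a hairpin, was tested as the difference of log2 fold changes over the root of the summed squared errors, with a normal reference and Benjamini-Hochberg adjustment. Overlap of calls was tested with Fisher's exact test, two-sided, per direction. The 16 fixed lists were tested with cameraPR of limma 3.58.1 (R 4.3.3) on the signed normal deviates, with a correlation of 0.01, over 28 tests of lists with 3 or more measured members, and again with 0.05, on ranks and without miR-7-5p. A correlation estimated from the libraries and fry were not run. The procedures were tested on simulated data with equal library totals, a known dispersion and normal p-values. The deposited fits had unequal totals and estimated dispersions, so the simulation does not check the errors printed here. Intervals held the true change for 93.9% to 95.5% of microRNAs at 10 CPM or more, and 84.8% to 95.4% of 2-fold changes at 10 CPM or more were called. Over all 837 or 868 simulated microRNAs, 3 and 7 unchanged ones were called for the first table and 3 and 0 for the second, at dispersions of 0.005 and 0.02. The difference test called 78.3% of 2-fold differences, and 2 unchanged microRNAs, in a simulation of 304.

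Named microRNAs were set by a rule fixed before the data were examined. It takes the miR-7 strands, up to 12 largest rises and 12 largest falls among calls with a mean of 1 CPM or more, the 3 most abundant calls, the 5 most abundant microRNAs, the measured members of the lists of endogenous decay substrates and reported ZSWIM8-sensitive microRNAs, and 2 to 4 examples of the other lists. The part of the rule that asks for non-overlapping libraries could not be applied. The miRNAs named beside a list as adjusted over the list alone, and those of the closing section, were chosen after their values were seen. Other settings tried were an adjusted p of 0.01, a minimum change of 1.5-fold, a minimum of 10 CPM, centring on the median or on a trimmed mean (30% cut at each end) and 4 denominator degrees of freedom. List members that are not among the rows, such as miR-30b-5p, miR-30c-5p and let-7a-5p, were not analysed here.

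Guide sequences from the labels were searched in the GENCODE 29 transcripts, and positions of genes are those of GENCODE 29 on GRCh38, not of the authors' build. Of 952 microRNAs in either table, 938 were matched by name to an annotated microRNA gene. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.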

Results

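MicroRNAs were measured by small-RNA sequencing in K562, a human erythroleukaemia cell line that grows in suspension and carries many features of erythroid and megakaryocytic precursors. The 12 libraries formed 4 groups of 3, described by the depositors as biological triplicates of each line. Cells with a guide RNA against the long non-coding RNA CYRANO (sgCYRANO) were set against cells with a non-targeting guide (sgNT), and cells lacking ZSWIM8 (ZSWIM8 KO), the substrate receptor of a Cullin-RING ubiquitin ligase, were set against the WT line. The series asks which microRNAs change when target-directed microRNA decay is disrupted, a process in which an extensively paired target RNA causes loss of the microRNA bound to it. CYRANO is such a target for miR-7.

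The values came as the authors' deposited tables of the 2 comparisons, with 837 microRNAs tested for sgCYRANO against sgNT and 868 for ZSWIM8 KO against WT, of which 753 were in both. No values of single libraries were used here. The fold changes were read as the second-named group over the first, since the table headers give no direction. Turned, the means and totals of both groups of a comparison would change places. Mean counts per 1000000 reads (CPM) of each group were recovered from the deposited columns. The totals of the 12 libraries, read from the smallest steps in these means, were 2300000, 1640000 and 1550000 reads for sgNT, 1850000, 1770000 and 1670000 for sgCYRANO, 1850000, 1100000 and 861000 for WT, and 2490000, 2480000 and 2090000 for ZSWIM8 KO. A group mean of 0 therefore allowed up to 0.546 CPM in sgNT, 0.567 in sgCYRANO, 0.788 in WT and 0.425 in ZSWIM8 KO, taking 3 counts over the group as the limit, which covers counting error only. Errors after ± are standard errors implied by the deposited p-values. The 10 most abundant microRNAs held 77.9% of all CPM in the first table and 77.5% in the second, and 299 and 304 microRNAs reached 10 CPM.

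The guide against CYRANO, CATCTCAAAATGGAAGACAT, matched 1 annotated transcript, in antisense, in OIP5-AS1, the annotated name of CYRANO. The match lay at chromosome 15, positions 41300590 to 41300609 of GRCh38, in exon 4 of this non-coding gene on the + strand, and spanned transcript positions 2885 to 2904 of 8829. The 3 bases next to the match on the guide's strand were TGG. The match covered the sequence GTCTTCC at transcript positions 2887 to 2893, which pairs with bases 2 to 8 of miR-7-5p, within the stretch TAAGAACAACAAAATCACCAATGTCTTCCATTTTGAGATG. The non-targeting guide matched 0 annotated transcripts. The mature miR-7-5p sequence TGGAAGACTAGTGATTTTGTTGTT lies in 3 annotated hairpins, MIR7-1 (chromosome 9, 83969748 to 83969857), MIR7-2 (chromosome 15, 88611825 to 88611934) and MIR7-3 (chromosome 19, 4770670 to 4770779). ZSWIM8 lies at chromosome 10, 73785582 to 73801797. The RNA levels of CYRANO and ZSWIM8 are not given by small-RNA tables, so the loss of either could not be checked here.

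The first comparison asked which microRNAs respond to disruption of CYRANO. In the authors' deposited table, miR-7-5p rose from a group mean of 6102 CPM in sgNT to 34884 CPM in sgCYRANO, a log2 fold change of 2.52 ± 0.09, or 5.72-fold (edgeR quasi-likelihood test, adjusted p = 5.03e-174). It was the 1 microRNA of 837 past an adjusted p of 0.05. The strand from the opposite arm of its first hairpin, miR-7-1-3p, had group means of 46.9 and 42.5 CPM, and a log2 fold change of -0.14 ± 0.18 with an adjusted p of 0.980 in the authors' deposited table. The change of miR-7-5p over miR-7-1-3p was 2.66 ± 0.20 on the log2 scale (adjusted p = 5.12e-37, normal test of the difference of both fold changes over 201 hairpins), the 1 arm difference past the threshold. Since miR-7-5p also lies in other annotated hairpins, this is not a change within 1 hairpin alone. With both arms at 10 CPM or more, 2 hairpins passed.

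The abundant microRNAs of these cells did not pass the test in sgCYRANO. In the authors' deposited table the log2 fold change was -0.13 ± 0.07 for miR-21-5p, -0.02 ± 0.07 for miR-92a-3p, -0.11 ± 0.07 for miR-148a-3p, 0.05 ± 0.07 for miR-146b-5p and -0.07 ± 0.07 for miR-26a-5p. Of the 141 other microRNAs at 100 CPM or more, 133 had a 95% interval within 1.5-fold in either direction. The implied degrees of freedom were most often 3348 in this comparison, so the variance was almost wholly shared between microRNAs. The errors and intervals therefore do not show each microRNA's own spread over the libraries. The next smallest adjusted p after miR-7-5p in the authors' deposited table was 0.140, for miR-210-3p, a hypoxia-induced microRNA, at -0.42 ± 0.12. Unadjusted p-values under 0.05 were found for 49 microRNAs, where 41.85 are expected with no effect.

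Among endogenous decay substrates (4 of 6 list members measured), 1 rose in sgCYRANO and 3 did not pass. Besides miR-7-5p, the authors' deposited table gave -0.28 ± 0.14 for miR-221-3p, -0.19 ± 0.12 for miR-222-3p and -0.16 ± 0.23 for miR-29b-3p. Of 12 measured microRNAs reported as sensitive to ZSWIM8, 1 rose and 11 did not pass, with -0.38 ± 0.17 for miR-503-5p and -0.27 ± 0.14 for miR-450b-5p in the authors' deposited table. Adjusted over the list alone, the count was 1 in each of these lists. Both lists passed the preset-correlation set test (limma cameraPR, adjusted p = 1.69e-16 and 0.00397), and the call rests on miR-7-5p, since on ranks the direction turned to lower with adjusted p-values of 0.466 and 0.102.

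None of the other 14 lists held a microRNA past the threshold over all microRNAs tested in sgCYRANO. Adjusted over the list alone, 1 erythroid strand (miR-210-3p), 1 miR-30 family strand (miR-30e-5p, -0.23 ± 0.09 in the authors' deposited table) and 1 non-haematopoietic marker (miR-9-5p, 0.31 ± 0.10 in the authors' deposited table) passed. The remaining measured members included let-7f-5p at 0.07 ± 0.09, miR-16-5p at -0.06 ± 0.10, miR-451a at 0.13 ± 0.10 and miR-486-5p at 0.04 ± 0.08 in the authors' deposited table.

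**Figure D1:**
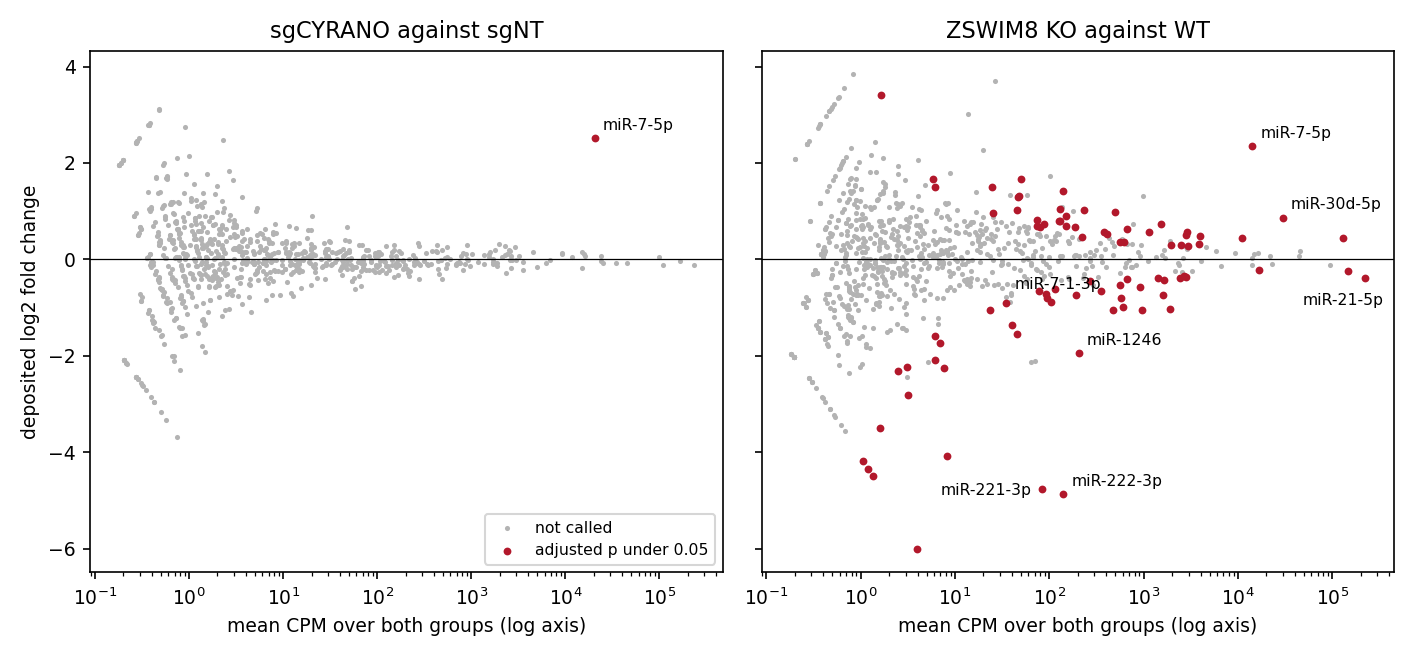
Deposited log2 fold change (vertical axis) against the mean CPM over both groups (horizontal axis, logarithmic) for sgCYRANO against sgNT and for ZSWIM8 KO against WT, with 1 point per microRNA. Red points have an adjusted p under 0.05, which holds for miR-7-5p alone of 837 in the first panel and for 86 of 868 in the second.

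The second comparison asked which microRNAs respond to loss of ZSWIM8. In the authors' deposited table, miR-7-5p rose from a group mean of 4617 CPM in WT to 23494 CPM in ZSWIM8 KO, a log2 fold change of 2.35 ± 0.14, or 5.09-fold (adjusted p = 8.48e-61, edgeR quasi-likelihood test). The pair miR-221-3p and miR-222-3p, neighbours on chromosome X that promote proliferation by repressing the cell cycle inhibitor p27, fell by far more than any other abundant microRNA. The authors' deposited table gave log2 fold changes of -4.76 ± 0.48 for miR-221-3p (159.8 to 5.76 CPM) and -4.88 ± 0.58 for miR-222-3p (270.7 to 9.10 CPM). In all, 86 of 868 microRNAs passed an adjusted p of 0.05, 41 higher and 45 lower, and 12 of these rises and 22 of these falls were 2-fold or more. Of the 86, 70 had a mean of 10 CPM or more and 16 a lower one.

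The median log2 fold change of microRNAs at 10 CPM or more was 0.13 in this comparison and -0.02 in the first. Relative to that median, 92 microRNAs passed, 30 higher and 62 lower, against 41 and 45 as deposited, and relative to a trimmed mean the counts were 29 and 63. Reading the deposited F with 4 denominator degrees of freedom left 3 calls, of which 1 was higher and 2 lower. That F rests on a variance shared between microRNAs, so the 3 calls do not show what each microRNA's own spread would leave.

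The passenger strand miR-7-1-3p did not rise with miR-7-5p. Its group means were 44.3 CPM in WT and 25.7 CPM in ZSWIM8 KO, and the authors' deposited table gave -0.78 ± 0.29 with an adjusted p of 0.067. The 5p strand changed by 3.13 ± 0.32 more than this 3p strand (normal test, adjusted p = 8.54e-20 over 209 hairpins), though miR-7-5p also lies in other hairpins. The adjusted p of miR-7-1-3p passed when microRNAs under 10 CPM were left out and when fold changes were centred on the median.

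The largest rise by log2 fold change among the calls was of a scarce microRNA. In the authors' deposited table miR-6894-3p, at 0.180 CPM in WT and 3.13 CPM in ZSWIM8 KO, had 3.42 ± 1.10, a value that rests on a WT mean below the limit of 3 counts. At 10 CPM or more the authors' deposited table gave 1.67 ± 0.28 for miR-1301-3p, 1.43 ± 0.26 for miR-9-3p, 1.31 ± 0.27 for miR-1307-5p, 1.30 ± 0.28 for miR-574-5p and 1.03 ± 0.27 for miR-574-3p. The group means of miR-542-3p, a call of the Xq26 cluster, were 12.7 and 36.2 CPM, a 2.83-fold rise. Further rises in the authors' deposited table were miR-3177-3p (1.66 ± 0.51), miR-10399-3p (1.51 ± 0.51), miR-450b-5p (1.04 ± 0.20) and miR-105-5p (1.01 ± 0.17). The rise of miR-10399-3p was no longer called after centring on the median.

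Besides miR-221-3p and miR-222-3p, the falls included both 5p strands of that cluster. miR-221-5p went from 15.5 to 0.805 CPM, with -4.07 ± 0.63 in the authors' deposited table, while miR-222-5p had 2.41 CPM in WT and a mean of 0 in ZSWIM8 KO. Its WT mean was 5.67 times the ZSWIM8 KO limit of 3 counts. A mean of 0 in ZSWIM8 KO was also found for miR-1263 (7.89 CPM in WT, 18.6 times the limit), miR-7706 (2.69 CPM, 6.32 times) and miR-4761-3p (2.13 CPM, 5.01 times). These ratios leave out the error of the WT means and are not lower bounds of the falls. At low levels the authors' deposited table gave -3.49 ± 1.15 for miR-6503-3p, -2.82 ± 0.77 for miR-31-5p, -2.32 ± 0.82 for miR-4772-3p, -2.25 ± 0.51 for miR-944 and -2.23 ± 0.73 for miR-556-5p. The KO means of miR-6503-3p, at 0.159 CPM, lay under the limit of 3 counts.

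The 3 called microRNAs of highest abundance changed by less than 1.5-fold. In the authors' deposited table miR-21-5p fell by 0.38 ± 0.07 on the log2 scale (adjusted p = 5.67e-07), miR-92a-3p fell by 0.24 ± 0.07 (adjusted p = 0.0057) and miR-148a-3p rose by 0.43 ± 0.07 (adjusted p = 4.31e-08). The other abundant strands miR-146b-5p and miR-126-3p had -0.12 ± 0.07 and 0.17 ± 0.07 in the authors' deposited table and did not pass. The rise of miR-30d-5p, from 21115 to 38430 CPM, was 0.86 ± 0.09 in the authors' deposited table (adjusted p = 4.03e-20).

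Of 4 measured endogenous decay substrates, 1 rose, 2 fell and 1 did not pass in ZSWIM8 KO. The authors' deposited table gave 0.45 ± 0.34 for miR-29b-3p, the member that did not pass. Of 12 measured microRNAs reported as sensitive to ZSWIM8, 5 rose, 2 fell and 5 did not pass, and adjusted over the list alone the counts were the same. The list was assembled partly from studies of ZSWIM8 loss, and is not independent evidence of direction. Its median log2 fold change was 0.77 and its mean -0.03, and the set test called it higher (limma cameraPR, adjusted p = 0.028), which was lost with a correlation of 0.05 (adjusted p = 0.086), on ranks (adjusted p = 0.0765) and without miR-7-5p (adjusted p = 0.790), on which it rests. The list of decay substrates was not called as a whole (limma cameraPR, adjusted p = 0.972). Without miR-7-5p its 3 remaining members were called lower (limma cameraPR, adjusted p = 9.44e-06). That call rests on miR-221-3p and miR-222-3p, since miR-29b-3p had a positive change.

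Of 6 measured strands of the Xq26 cluster, whose microRNAs act on cell cycle genes, 4 rose and 2 did not pass, and adjusted over the list alone likewise 4 rose. These 4 are also among the 5 rises of the ZSWIM8-sensitive list. The set test called the cluster higher (limma cameraPR, adjusted p = 0.00397, and 0.013 with a correlation of 0.05), which was lost on ranks (adjusted p = 0.0765). Besides miR-542-3p and miR-450b-5p, the authors' deposited table gave 0.90 ± 0.19 for miR-450a-5p and 0.82 ± 0.23 for miR-503-5p, against 0.31 ± 0.25 for miR-424-5p and -0.27 ± 0.35 for miR-424-3p, which did not pass. The hairpins lie between positions 134540185 and 134546711 of chromosome X in GRCh38, on the - strand.

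In the miR-30 family 1 of 3 measured strands rose, and adjusted over the list alone 2 rose and 1 fell. The authors' deposited table gave 0.76 ± 0.28 for miR-30a-5p and -0.24 ± 0.10 for miR-30e-5p. The set test called the family higher (limma cameraPR, adjusted p = 0.028, and 0.048 with a correlation of 0.05), and on ranks its adjusted p was 0.488. The call rests mainly on miR-30d-5p, with a signed normal deviate of 9.75, against 2.74 for miR-30a-5p and -2.47 for miR-30e-5p.

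Of 12 measured strands from miR-17~92 and its paralogous clusters, which promote proliferation, 4 fell and 8 did not pass, and adjusted over the list alone 6 fell and 1 rose. The authors' deposited table gave -0.35 ± 0.10 for miR-19a-3p, -0.42 ± 0.11 for miR-19b-3p and -0.23 ± 0.08 for miR-25-3p beside the fall of miR-92a-3p. miR-20a-5p, at -0.09 ± 0.08, and miR-17-5p, at 0.13 ± 0.08 in the authors' deposited table, did not pass. The set test called the list lower with an adjusted p of 0.048 (limma cameraPR), which was lost with a correlation of 0.05 (adjusted p = 0.137) and on ranks (adjusted p = 0.0765).

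In the let-7 family, which represses proliferation genes, 2 of 7 measured strands rose and 5 did not pass, and adjusted over the list alone 4 rose and 1 fell. The authors' deposited table gave 0.56 ± 0.13 for let-7g-5p and 0.32 ± 0.10 for let-7f-5p, and the call for let-7f-5p was lost after centring on the median. The set test did not call the family (limma cameraPR, adjusted p = 0.093). Of 12 megakaryocytic and myeloid strands 3 fell and 9 did not pass, and adjusted over the list alone 5 fell and 2 rose. The authors' deposited table gave -1.36 ± 0.29 for miR-99a-5p, -2.09 ± 0.53 for miR-125b-5p and -0.38 ± 0.10 for miR-223-5p, and the set test gave an adjusted p of 0.093 (limma cameraPR).

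Among 6 erythroid strands, 1 fell (miR-486-3p, -0.40 ± 0.14 in the authors' deposited table) and 5 did not pass, with the count adjusted over the list alone also 1. The most abundant, miR-486-5p, had -0.11 ± 0.22 and miR-451a 0.73 ± 0.62 in the authors' deposited table, and their errors, here taken from the deposited F, were 2.25 and 4.43 times those of microRNAs of like abundance. The lists of miR-15/16 (1 of 7 rose, miR-503-5p), miR-29 (0 of 3), lymphoid (0 of 4), non-haematopoietic (1 of 11 fell, miR-21-5p), 14q32 (0 of 20) and Drosha- or Dicer-independent (0 of 5) strands were not called by the set test, with adjusted p-values of 0.504, 0.622, 0.895, 0.972, 0.169 and 0.438 (limma cameraPR). Adjusted over the list alone, 1 strand passed in the miR-15/16, miR-29 and non-haematopoietic lists each, 2 in the lymphoid list and 0 in the others. Of the 2 measured strands targeted by viral decay RNAs 0 passed.

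**Figure D2:**
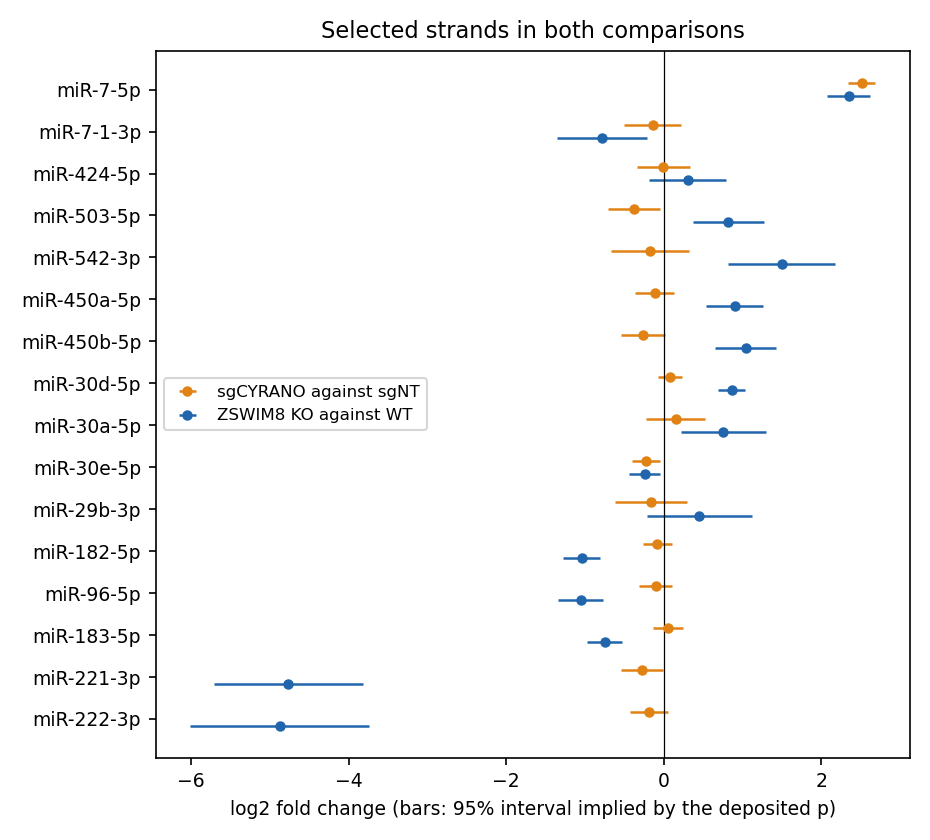
Log2 fold change (horizontal axis) of 16 strands in sgCYRANO against sgNT (orange) and ZSWIM8 KO against WT (blue), with bars showing the 95% interval implied by the deposited p. Both comparisons place miR-7-5p above 2, and miR-221-3p and miR-222-3p lie below -4 in ZSWIM8 KO alone.

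The arms of a hairpin were compared because decay of a loaded strand alters 1 arm, while altered transcription of the hairpin alters both. Altered processing can do either. A strand shared by several hairpins, such as miR-7-5p, miR-16-5p or miR-92a-3p, can also change through another hairpin. In ZSWIM8 KO 11 of 209 hairpins had an arm difference past the threshold, 6 with the 5p arm higher relative to the 3p arm and 5 with the reverse. After miR-7-1, the smallest adjusted p-values belonged to miR-92a-1 (-0.81 ± 0.14, adjusted p = 2.03e-06), miR-223 (-0.68 ± 0.15, adjusted p = 0.000712), miR-671 (1.12 ± 0.27), miR-148a (-0.60 ± 0.14) and miR-130b (-0.69 ± 0.17), the last 3 with the same adjusted p of 0.00125, each as 5p minus 3p. The test ignores the covariance of both arms within a library, which was not measured here.

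The effects of both perturbations were then set against each other over the 753 shared microRNAs. For miR-7-5p the ZSWIM8 KO effect minus the sgCYRANO effect was -0.17 on the log2 scale, with a 95% interval from -0.49 to 0.16 (adjusted p = 0.766, normal test). The difference passed for 50 microRNAs, 28 higher and 22 lower in ZSWIM8 KO. The smallest adjusted p-values were those of miR-221-3p (-4.49 ± 0.50, adjusted p = 3.30e-16), miR-222-3p (-4.69 ± 0.59, adjusted p = 8.01e-13), miR-1246 (-1.84 ± 0.23, adjusted p = 8.01e-13), miR-92a-1-5p (-1.25 ± 0.16, adjusted p = 8.01e-13) and miR-30d-5p (0.78 ± 0.12, adjusted p = 4.25e-09). Reads of miR-1246 can also stem from U2 small nuclear RNA. Of the calls among shared microRNAs 1 was common to both comparisons, miR-7-5p, where 0.0544 were expected of independent lists (Fisher's exact test, two-sided, p = 0.054 for rises). With 1 call in the first comparison this test cannot fall under 0.0544, and no libraries were shared.

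**Figure D3:**
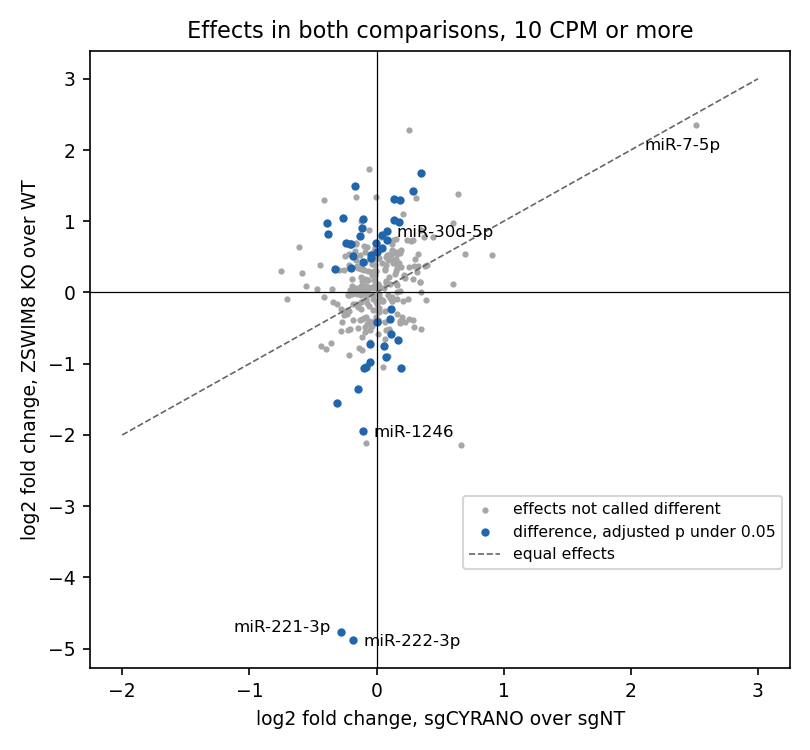
Log2 fold change in ZSWIM8 KO over WT (vertical axis) against sgCYRANO over sgNT (horizontal axis) for the 294 microRNAs at 10 CPM or more in both tables. The dashed line marks equal effects, and the 45 blue points differ between the comparisons past an adjusted p of 0.05, with miR-7-5p close to the line and miR-221-3p and miR-222-3p far below it.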

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

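The test of the difference between both perturbations, the test of scaling for the miR-221 and miR-222 falls, the condition that partner strands pass both before and after centring, the counting of each hairpin once, and the count of hairpins with an arm difference, were chosen after the values had been seen. The effects of ZSWIM8 KO and sgCYRANO differed for 50 of 753 microRNAs (normal test of the difference, adjusted p under 0.05). The differences of smallest adjusted p, as ZSWIM8 KO minus sgCYRANO on the log2 scale, were -4.49 for miR-221-3p, -4.69 for miR-222-3p, -1.84 for miR-1246, -1.25 for miR-92a-1-5p and 0.78 for miR-30d-5p.

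The first pattern weighed is the set of falls in ZSWIM8 KO led by miR-221 and miR-222. The scaling offset seen, a median shift of 0.13, was far smaller than the falls of miR-221 and miR-222. After centring, the 4 strands of this pair had a median log2 fold change of -4.68, with a largest standard error of 1.37. One of them, miR-222-5p, had a mean of 0 in ZSWIM8 KO. With so small a shift the outcome was fixed in advance, and it says nothing of the smaller falls. Over all calls, centring on the median turned 41 higher and 45 lower into 30 and 62. A change of the whole hairpin is consistent with part of the falls, since partner strands at 10 CPM or more had a median of -0.23 with each hairpin counted once (95% bootstrap interval -0.73 to -0.03 over 13 hairpins, and -0.07 for the 6 partners not themselves called, or -0.20 after centring), and both arms fell in miR-221 (-4.07 and -4.76). As the whole cause it is argued against, since 6 of the 13 hairpins had an arm difference past an adjusted p of 0.05. Of these, miR-16-2 and miR-92a-1 do not bear on the question, since miR-16-5p and miR-92a-3p can also stem from another hairpin. The others were miR-223, miR-671, miR-25 and miR-32. Their partners were miR-223-3p at 0.30, miR-671-5p, called as a rise, at 0.68, miR-25-3p at -0.23 and miR-32-5p at -0.005. Whether whole hairpins changed in transcription or in processing, and whether the lines differed before ZSWIM8 loss, stays open.

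The second pattern is the set of 40 called rises in ZSWIM8 KO other than miR-7-5p. Only scaling offsets near the median shift of 0.13 were tried, and with so small a shift the larger rises were bound to pass. An offset of that size is argued against as the whole cause, since 29 of the 40 still passed after centring on the median. Whether whole hairpins rose cannot be told apart from that offset: partner strands had a median of 0.21 with each hairpin counted once (95% bootstrap interval 0.06 to 0.53 over 17 hairpins), but after centring the interval ran from -0.07 to 0.40. As the whole cause it is argued against, since 4 of the 17 hairpins had an arm difference past an adjusted p of 0.05. Stabilisation of single strands by loss of ZSWIM8 stays open for the rises as a set.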

How the results depend on the processing

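Settings other than the minimum of 10 CPM, the stricter thresholds for the overlap and the minimum of 10 CPM for both arms were chosen after the data were seen. No paired analysis was possible because the tables carry no per-library values, and for the same reason the fits with TMM, DESeq2, limma-voom or filterByExpr, the replicate block, the left-out libraries, other pseudocounts, other splits of the samples and the estimated correlation were not run. The rise of miR-7-5p kept its direction and its call in both comparisons under every setting run, and the 1 call in sgCYRANO was kept by all 6. In ZSWIM8 KO the 86 calls became 56 at an adjusted p of 0.01 and 3 with 4 denominator degrees of freedom, both by construction. They became 59 with a minimum of 1.5-fold, 102 (62 higher, 40 lower) from 10 CPM upwards and 92 with either centring, which turned 41 higher and 45 lower into 30 and 62, or 29 and 63. The median centring shares 75 calls with the deposited ones. The 50 differences between perturbations became 29 at an adjusted p of 0.01. The 1 arm difference in sgCYRANO became 2 with both arms at 10 CPM or more, where 70 hairpins were tested. The 6 lists past the threshold became 4 with a correlation of 0.05, 3 without miR-7-5p and 0 on ranks, and the cause was not tested. Of 71 other named microRNAs in ZSWIM8 KO, centring on the median lost 2 calls and gained 5, and 4 degrees of freedom lost 31. None of the named microRNAs that were called changed direction. The shallowest group held 3810000 reads, which is WT as the fold changes were read and ZSWIM8 KO if turned, and limits what can be said of microRNAs at a few CPM in that comparison.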

Other observations

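The test of counting noise for the erythroid strands, with its adjustment over all lists, the counting of each hairpin once and the chromosome 19 strands were chosen after their values were seen. Beyond the lists, ZSWIM8 KO had lower levels of the miR-183 cluster, 3 hairpins between positions 129770383 and 129775014 of chromosome 7 in GRCh38 that are known from sensory organs. The authors' deposited table gave -1.04 ± 0.12 for miR-182-5p, -1.05 ± 0.14 for miR-96-5p and -0.75 ± 0.11 for miR-183-5p. Further falls in the authors' deposited table were those of miR-1246 (-1.94 ± 0.20), miR-215-5p (-1.55 ± 0.29) and miR-25-5p (-0.98 ± 0.17), and further rises those of miR-135b-5p (0.99 ± 0.14) and miR-340-5p (0.73 ± 0.11).

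Neighbouring hairpins with called strands tended to change in the same direction in ZSWIM8 KO. Among called microRNAs, 17 of 19 pairs of hairpins within 10 kb on the same strand shared their sign, where permuted signs gave 9.39 on average (permutation test, one-sided, p = 0.00287, 100000 draws). The pairs that did not were miR-24-3p, which rose, with miR-27a-5p and with miR-27b-5p, which fell. Most pairs came from the miR-17~92 and Xq26 clusters, and strands not called were left out of the test. Of the listed members of these clusters that were not called, miR-17-5p (0.13) and miR-424-3p (-0.27) went against their cluster. Those that went with it were miR-17-3p (-0.42), miR-20a-5p (-0.09) and miR-424-5p (0.31). A candidate explanation for part of the calls is altered transcription of clusters, a hypothesis that the tables cannot separate from effects on the mature strands.

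The third pattern is the wide spread of erythroid microRNAs in the WT and ZSWIM8 KO libraries. The errors of the 6 strands, taken from the deposited F, had a median of 2.43 times those of microRNAs of like abundance, above 99.99% of 10000 random lists matched on abundance, against 0.995 in the other comparison. In that other comparison the variance was almost wholly shared between microRNAs, with implied degrees of freedom most often 3348. Ratios near 1 there are largely set by the fit and do not show an ordinary spread. Counting noise at low abundance would be shared by strands of like abundance and is argued against for the list, which passed as 1 of 25 tests of lists over both comparisons (one-sided, adjusted p = 0.00525, 100000 random lists each). The ratio was 4.43 for miR-451a, 2.76 for miR-144-3p and 2.25 for miR-486-5p, a strand of 13918 CPM, while miR-486-3p and miR-210-3p lay at 1.04 and 0.990. The list holds both strands of the miR-144 and of the miR-486 hairpin, and the random lists were matched on abundance alone. The adjusted p therefore overstates the support for a spread of 6 separate erythroid microRNAs. Cells of another type in some libraries would be expected to widen non-haematopoietic markers too. The errors of 4 such markers met this, with a median of 1.96 above 98.07% of random lists (95th percentile 1.09), not adjusted for other lists. It was carried by miR-375-3p (3.77) and miR-9-5p (2.92) and not by miR-200c-3p (0.991) or miR-200b-3p (0.988). The whole list, with miR-126-3p and miR-21-5p, had a median of 0.989 and did not pass (one-sided test against random lists, adjusted p = 0.619). Cells of another type are therefore neither shown nor excluded. A difference between cultures or clones of a line, which could widen the same strands, stays open and was not tested, since no values of single libraries were used.

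Spread in that comparison was also wide in microRNAs of the chromosome 19 cluster, which is known from placenta. All 7 of its strands at 10 CPM or more had errors at least 3.32 times those of like abundance, up to 7.23 times for miR-512-3p, and their median was 4.58, against 1 for the 6 of them at 10 CPM or more in the other comparison. As for the erythroid strands, the value of 1 is largely set by the fit. The authors' deposited table gave 1.34 for miR-512-3p and 1.30 for miR-516b-5p, and neither passed the test.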
